A study of Homo sapiens with 6 samples.

How the data were processed

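RNA was measured in 6 samples of LNCaP, an established human prostate cancer cell line that is sensitive to androgen. Per the labels, cells were stained with ALDEFLUOR, a fluorescent substrate of aldehyde dehydrogenase, and sorted into the 10% with the highest and the 10% with the lowest signal, named ALDH high and ALDH low, with 3 samples each. Both were grown in RPMI-1640 medium with 10% fetal bovine serum. The time between sorting and RNA extraction is not given in the sources used here. Per the labels, mRNA was selected by its poly(A) tail before sequencing, and each gene's hits were counted from uniquely placed reads in its exons. Whether the libraries kept strand is left open by the labels, so reads of a gene and of an antisense neighbour cannot be told apart here. Counting of uniquely placed reads loses reads of genes with near-identical copies, among them ribosomal protein genes with processed pseudogenes.

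Per the submitters' processing notes, the tools were Trimmomatic 0.36, STAR 2.5.2b, featureCounts from Subread 1.5.2 and DESeq2, with the genome build GRCh38. The annotation release is not given in the sources used here. The authors deposited 1 table with a normalized signal per gene and sample, which is the gene's read count divided by 1 size factor per sample. The deposited table also holds the authors' log2 fold change, which is positive where ALDH low is higher, and the authors' p-value with its Benjamini-Hochberg adjusted value. The sign of that log2 fold change was read from the sample columns, since the log2 ratio of the group means had a Pearson r of 1.00 with it across genes.

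The table held 16046 rows, of which 46 were ERCC spike-in sequences and 16000 were genes. The lowest mean of a row was 9.65 normalized reads, so the table starts at a minimum mean and the totals below cover its listed rows only. Spreadsheet software had turned 21 gene names into dates, and 45 genes had no name. These names were restored from the gene identifiers with GENCODE release 29, which matched 15939 of the 16000 identifiers and gave the coordinates (GRCh38, counted from 1), exon lengths and GC content used here.

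Each sample's values were whole multiples of 1 step, which allowed the whole reads to be recovered. At least 99.99% of the values of each sample came out whole within 0.02 of a read. The recovered totals ran from 23817310 to 30617873 reads per sample.

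The design fixed before the data were examined assumed raw counts and named limma on log2(value + 1) for the case that the table held normalized values. That test was therefore the main one: limma 3.58.1 in R 4.3.3 with a mean-variance trend on log2(normalized count + 1), all 16000 genes, no further filter, and Benjamini-Hochberg adjustment with a threshold of 0.05. Differences are ALDH high minus ALDH low on that scale, which understates the change of low genes. Intervals are 95% intervals from the limma fit. The quasi-likelihood test of edgeR 4.0.16 on the recovered reads, which was the planned test for counts, was run as an alternative, as were DESeq2 1.42.0 and limma-voom. Nothing in the labels says that the 3 samples of a group came from separate sorts, so p-values measure only the spread between these samples.

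Gene lists were also fixed before the data were examined, 41 in all. The 38 lists with at least 5 genes in the table were tested with camera, which compares the genes of a list with all others, at its preset correlation of 0.01, and adjusted over the lists. Camera with a correlation estimated from the data and fry were run beside it. Gene names were printed by a rule fixed at the same time. It covers every aldehyde dehydrogenase gene of the table, KLK3 and another gene that is not reported here, the 6 genes with the largest increase and the 6 with the largest decrease among genes past the threshold with a mean of at least 5 CPM and no overlap between groups, and up to 3 genes past the threshold with a mean of at least 1 CPM from each called list and from the lists of androgen-induced genes, luminal, basal, neuroendocrine, stem, mesenchymal and retinoid genes. No gene passed the threshold, so only the aldehyde dehydrogenases and KLK3 were named by the rule. All other genes in the text were chosen after their values were seen. ALDH1A1 and ALDH3A1, which the rule names, were not among the 12 aldehyde dehydrogenase genes found in the table and were not analysed here.

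Sample structure was described with the principal components of log2 CPM (prior count 2) of the 500 most variable genes and with Pearson correlations across genes. Single measures of a library were compared with two-sided exact permutation tests, whose smallest possible p with 3 samples against 3 is 0.1. Pairs of libraries were checked for duplicates by a chi-square statistic per gene on the recovered reads. Its mean over genes was 5.32 for ALDH high 1 with ALDH high 3, 5.31 for ALDH high 1 with ALDH low 2, 10.0 for ALDH high 3 with ALDH low 2, and 41.8 to 91.7 for every other pair, where sampling noise alone gives about 1. No pair agreed within sampling noise, so the libraries were counted as 6 samples as labelled, although repeat libraries of 1 RNA can also exceed that noise.

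The tests were tested on simulated data with the 16000 genes' means and the libraries' sizes, a median biological coefficient of variation of 19.9%, and 100 genes changed 2-fold and 100 changed 4-fold. Each gene was drawn independently, so the simulated libraries lacked the arrangement across the labels that is described below. Limma recovered 51 of the 2-fold and 87 of the 4-fold changes with 9 false calls. Alternatives planned before the data were examined were pseudocounts of 0.1 and 0.5, other size factors, a filter of 1 CPM in at least 3 samples, the other tests, a test against a 1.5-fold change, the replicate number as a block, each replicate left out, and the 10 most abundant genes left out. The fit without a filter, also listed beforehand, is the main test itself. Alternatives added after seeing the data were edgeR on the recovered reads with and without the block, TMM factors on the recovered reads, no mean-variance trend, removal of a trend with gene length and GC content (splines with 4 degrees of freedom, 15931 genes), both samples numbered 2 left out, and mitochondrial genes left out.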

Results

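Poly(A) RNA was sequenced from LNCaP cells sorted by aldehyde dehydrogenase activity, with 3 samples of the 10% brightest cells in the ALDEFLUOR assay (ALDH high) and 3 of the 10% dimmest (ALDH low). Aldehyde dehydrogenases oxidise aldehydes, among them retinal, and high activity in this assay is widely used to enrich cells with stem-like traits. The deposited table gave normalized read counts for 16000 genes, of which 12683 are annotated as protein-coding. Recovered reads, with those of spike-in sequences, numbered 25538722, 28766265 and 23817310 in ALDH high 1, 2 and 3, and 30617873, 27042022 and 27979785 in ALDH low 1, 2 and 3. The comparison asks which genes differ in expression between ALDH high and ALDH low LNCaP cells.

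The samples did not separate by group. The first principal component held 69.7% of the variance of the 500 most variable genes and placed ALDH high 1, ALDH high 3 and ALDH low 2 at scores of 20.8, 21.2 and 19.1, and ALDH high 2, ALDH low 1 and ALDH low 3 at −17.2, −20.7 and −23.1. Across genes, ALDH low 2 correlated with ALDH high 1 at r = 0.992 and with ALDH high 3 at r = 0.991, and with ALDH low 1 and ALDH low 3 at 0.976 and 0.973. ALDH high 2 had its highest correlation with ALDH low 1 (r = 0.987), followed by ALDH low 2 (0.980), ALDH high 1 (0.9775), ALDH high 3 (0.9770) and ALDH low 3 (0.9768). Genes with large weights on this component, chosen after their values were seen, follow its arrangement by construction and are given as illustration. MAF, a transcription factor gene (chromosome 16, 79585843 to 79600714), had 319 and 307 normalized reads in ALDH high 1 and 3 and 264 in ALDH low 2, and 2288, 1792 and 1792 in ALDH high 2, ALDH low 1 and ALDH low 3. BMP5, which encodes a bone morphogenetic protein (chromosome 6, 55753645 to 55875564), had 792 and 745 in ALDH high 1 and 3 and 758 in ALDH low 2, and 77.6, 101.4 and 93.2 in the other libraries in the same order.

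**Figure D1:**
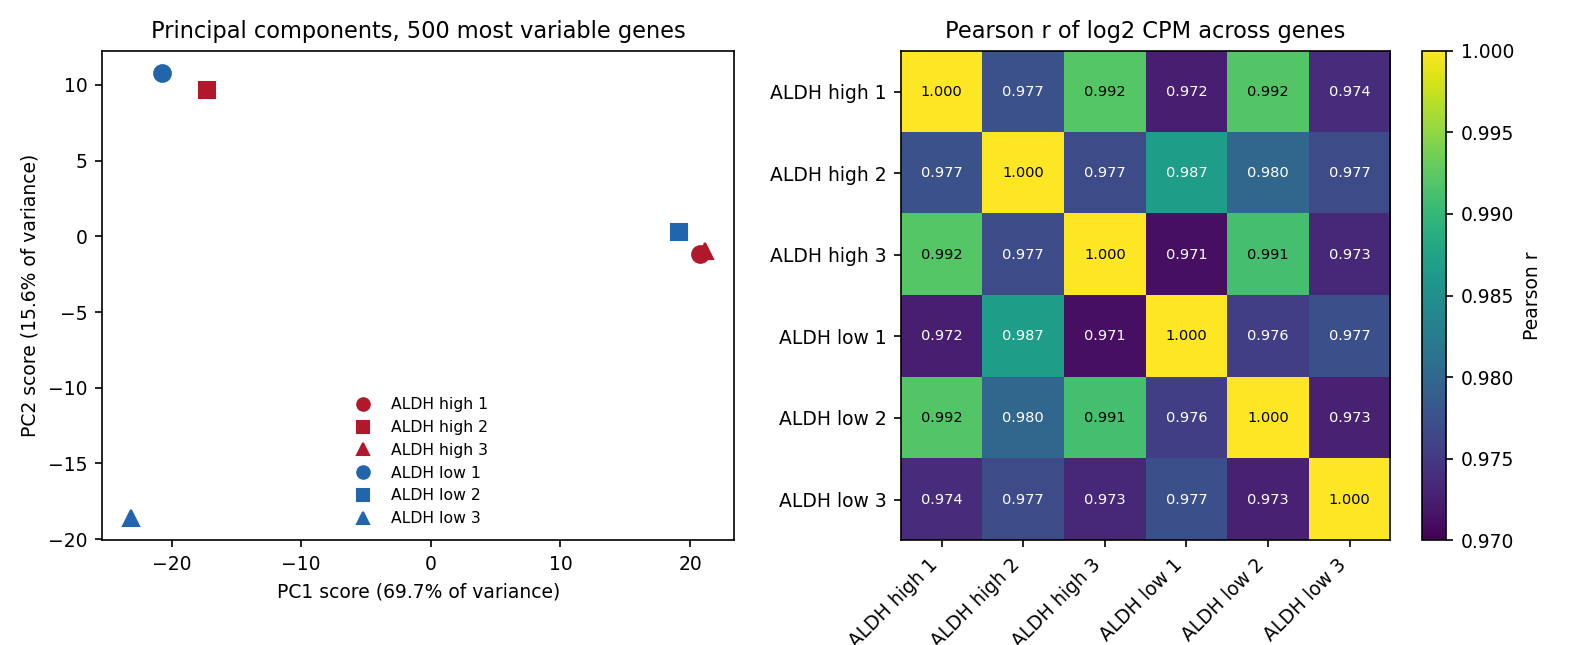
Left, scores of the 6 libraries on the first 2 principal components of log2 CPM of the 500 most variable genes, with the share of variance on each axis (red, ALDH high; blue, ALDH low; marker shape, replicate number). Right, Pearson r of log2 CPM across genes for each pair of libraries; ALDH high 1, ALDH high 3 and ALDH low 2 lie together with r of 0.991 to 0.992.

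**Figure D2:**
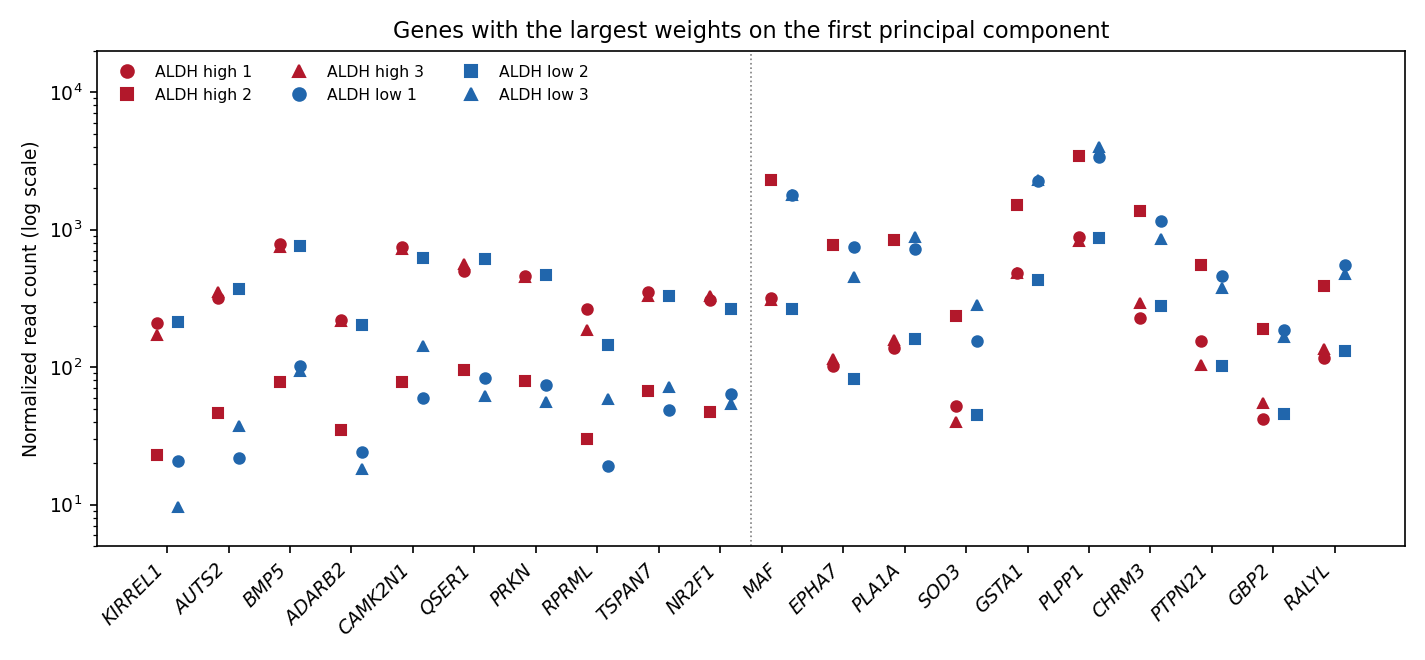
Normalized read counts (log scale) per library of the 10 genes with the largest positive (left of the dotted line) and the 10 with the largest negative weight on the first principal component, among named genes with a mean of at least 100 (red, ALDH high; blue, ALDH low; marker shape, replicate number; no means drawn). ALDH high 1, ALDH high 3 and ALDH low 2 lie on one side and ALDH high 2, ALDH low 1 and ALDH low 3 on the other, as for MAF, at 264 to 319 against 1792 to 2288 reads.

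Between the groups as labelled, no gene passed an adjusted p of 0.05. Limma called 0 of 16000 genes, with a smallest adjusted p of 0.984, and edgeR, DESeq2 and limma-voom on the recovered reads also called 0. At an unadjusted p under 0.05 limma counted 338 genes, edgeR 350, DESeq2 355 and limma-voom 337, where 5% of the genes tested with limma are 800. The authors' deposited table gives 0 rows with an adjusted p under 0.05, a smallest adjusted p of 0.998, and 355 rows with an unadjusted p under 0.05. The groups did not overlap in 588 genes that were higher and 531 that were lower in ALDH high, together 6.99% of genes, where chance gives 10% for 3 samples against 3. Of the 11506 genes with a mean of at least 100 normalized reads, 94.2% had a 95% interval that lay within a 2-fold change either way, and the median half-width of the interval was 0.42 on the log2 scale. With both samples numbered 2 left out, a choice made after seeing the data, limma called 107 genes between the remaining 4 libraries, 75 higher and 32 lower in ALDH high. All 107 were also called by the split of ALDH high 1, ALDH high 3 and ALDH low 2 against the others. In 107 of them ALDH low 2 lay nearer to the ALDH high samples, and in 103 ALDH high 2 lay nearer to the ALDH low samples. That split keeps the remaining 4 libraries on the same sides, so the overlap in calls is partly built in. The genes follow the arrangement across the labels, whose cause is not known. They cannot tell a difference between the groups from another cause of that arrangement, and are no separate evidence of such a difference. Leaving out any of the other 8 pairs of 1 library per group gave 0.

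Among genes with a mean of at least 5 CPM, chosen after their values were seen, those with the smallest unadjusted p differed by less than 2-fold. TAGLN, an actin-binding protein gene of smooth muscle and mesenchymal cells (chromosome 11, 117199321 to 117204782), averaged 173 ± 20.1 normalized reads in ALDH high and 102 ± 23.6 in ALDH low (SD, n = 3 each), a log2 difference of 0.77 (95% interval 0.23 to 1.32). NOTCH3, a Notch receptor gene (chromosome 19, 15159038 to 15200981), averaged 3919 ± 88.9 and 2858 ± 642. Its unadjusted limma p was 0.018, above those of MT-TL1 (0.011), SRRM2 (0.014) and MMP25-AS1 (0.016), which were also higher in ALDH high. NDUFAF4, an assembly factor of respiratory complex I (chromosome 6, 96889313 to 96897881), averaged 804 ± 43.3 in ALDH high and 1171 ± 190 in ALDH low, a log2 difference of −0.53 (−0.89 to −0.17). The limma adjusted p of TAGLN, NOTCH3 and NDUFAF4 was 0.984.

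Of the 19 aldehyde dehydrogenase genes listed, 12 were in the table and none passed limma's threshold over all genes, with 0 also when adjusted over the list alone. In 6 of them the log2 difference lay above 0 and in 6 below, and every 95% interval included 0. Without ALDH low 3 the sign turned in 4 of them, to −0.002 in ALDH1A3, 0.03 in ALDH2, 0.04 in ALDH9A1 and 0.01 in ALDH16A1, and it turned in ALDH6A1 without ALDH high 1 (0.02), without ALDH high 3 (0.07), with total-count scaling (0.01) and with mitochondrial genes left out (0.03). For 11 of the 12, all but ALDH1L1, the interval lay within a 2-fold change either way. ALDH1A3, a retinaldehyde dehydrogenase often linked to ALDEFLUOR signal (chromosome 15, 100877714 to 100916626), averaged 118 ± 13.2 normalized reads in ALDH high and 107 ± 25.6 in ALDH low (SD, n = 3 each), a log2 difference of 0.15 with a 95% interval of −0.41 to 0.72. An antisense gene overlaps 27.5% of its exon bases. ALDH2, the mitochondrial acetaldehyde dehydrogenase (chromosome 12, 111766887 to 111817529), averaged 55.4 ± 7.51 and 65.3 ± 20.1, a log2 difference of −0.20 (−0.89 to 0.50). The most abundant members were ALDH18A1, an enzyme of proline synthesis, at 4610 ± 391 and 4141 ± 512, ALDH1B1 at 3393 ± 19.4 and 3186 ± 328, ALDH9A1 at 3119 ± 465 and 3267 ± 445, and ALDH3A2, a fatty aldehyde dehydrogenase, at 2721 ± 168 and 2564 ± 296. ALDH3B2 (chromosome 11, 67662162 to 67681200) had the largest positive difference, 0.43 (−0.03 to 0.89), with 895, 744 and 940 normalized reads in ALDH high and 580, 852 and 515 in ALDH low. ALDH1L1 had the largest negative one, −0.72 (−2.004 to 0.56), at 7.26 ± 4.06 and 12.6 ± 6.15. ALDH3B1, ALDH4A1, ALDH6A1 and ALDH16A1 differed by 0.17, −0.23, −0.03 and −0.19, and 41.1% of the exon bases of ALDH4A1 are shared with an overlapping gene on the same strand. As a list, the aldehyde dehydrogenases had a median difference of 0.03, a mean of −0.03 and a camera adjusted p of 0.954.

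**Figure D3:**
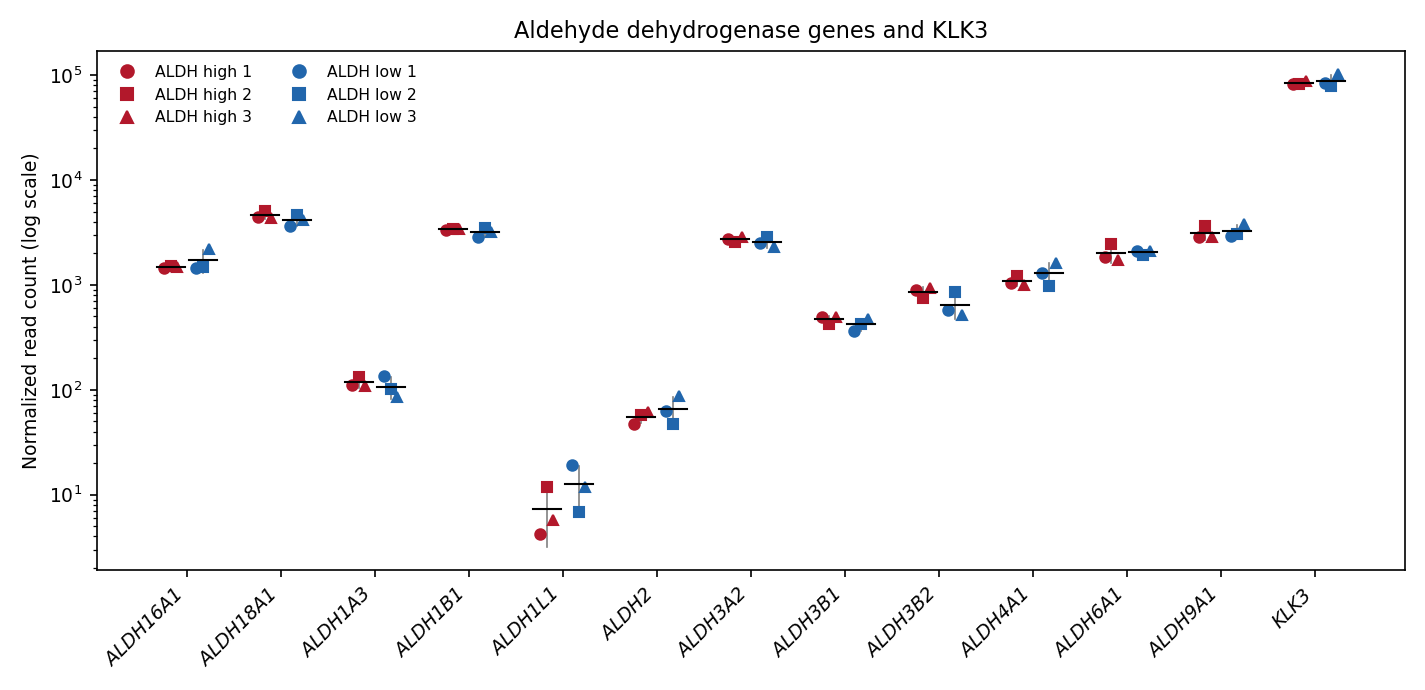
Normalized read counts (log scale) per library of the 12 aldehyde dehydrogenase genes and KLK3 (red, ALDH high; blue, ALDH low; marker shape, replicate number; black line, group mean; grey line, SD; n = 3). The groups overlap in each of the 13 genes, as for ALDH1A3, at 110 to 133 reads in ALDH high and 84.6 to 135 in ALDH low.

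KLK3, which encodes prostate-specific antigen and is induced by androgen (chromosome 19, 50854915 to 50860764), averaged 84410 ± 3629 normalized reads in ALDH high and 87807 ± 12287 in ALDH low (SD, n = 3 each), a log2 difference of −0.05 (95% interval −0.50 to 0.41), which was 0.06 without ALDH low 3 and 0.01 with mitochondrial genes left out. Of 44 androgen-induced genes in the table, 17 had differences above 0 and 27 below, with a median of −0.07 and a camera adjusted p of 0.0907, and none passed limma's threshold over all genes or adjusted over the list alone. The 11 androgen-repressed genes had a median of 0.09 and an adjusted p of 0.877, while camera's direction was downward. Among luminal markers, HOXB13 averaged 18162 ± 841 in ALDH high and 19966 ± 2605 in ALDH low, and KRT18 12865 ± 1219 and 12552 ± 4062. The list of 15 luminal markers had a median of 0.08 and a camera adjusted p of 0.547.

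Lists of other cell states were not called by camera either. The table held 15 of 31 stem and progenitor, 10 of 20 basal and 6 of 28 neuroendocrine symbols. It also held 17 of 39 retinoid, 13 of 30 mesenchymal and 7 of 23 androgen-independent ones, so these lists were tested in part. The 15 stem and progenitor markers had a median difference of 0.15 (adjusted p = 0.287), with 10 above 0 and 5 below. Among them SOX9 averaged 169 ± 95.3 in ALDH high and 105 ± 115.8 in ALDH low, and had 233, 59.3 and 215 reads in ALDH high 1, 2 and 3 and 39.9, 239 and 37.5 in ALDH low 1, 2 and 3. The 10 basal markers had a median of 0.06 (adjusted p = 0.547), the 6 neuroendocrine markers 0.36 (adjusted p = 0.454), and the 17 retinoid genes 0.05 (adjusted p = 0.96, with camera's direction downward). The 13 mesenchymal markers had a median of −0.02 and a mean of 0.08, in camera's direction (adjusted p = 0.307). The 20 Notch pathway genes had a median of 0.12 (adjusted p = 0.146), the 18 ABC transporters, some of which export drugs, 0.11 (adjusted p = 0.0907), and the 7 markers of androgen-independent prostate lines 0.38 (adjusted p = 0.117). Over all 41 lists, limma called 0 members among all genes tested and 0 adjusted over the list alone.

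Camera with its preset correlation called 7 of the 38 lists tested, 4 higher and 3 lower in ALDH high, and none of them held with an estimated correlation. All 50 cytosolic ribosomal protein genes had differences below 0, with a median of −0.21 (adjusted p = 3.43e-09, and 0.628 with an estimated correlation). RPL5 averaged 25526 ± 561 in ALDH high and 34025 ± 6654 in ALDH low (SD, n = 3 each). Of 50 nuclear genes of oxidative phosphorylation, 44 lay below 0, with a median of −0.15 (adjusted p = 4.95e-06, and 0.657 with an estimated correlation). Of 25 cholesterol synthesis genes, 24 lay below 0, with a median of −0.23 (adjusted p = 1.68e-05, and 0.628 with an estimated correlation). IDI1, an enzyme of isoprenoid synthesis, averaged 1780 ± 266 and 2724 ± 1102, and INSIG1, a regulator of the pathway, 4826 ± 1428 and 6685 ± 2619. For these 3 lists the call was lost without ALDH low 3, with medians of −0.03, 0.01 and −0.13. The cholesterol list kept its call at −0.13 without ALDH low 1, and at −0.45 without ALDH high 2 and −0.46 without ALDH low 2.

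The other 4 called lists were higher in ALDH high. Of 13 protein-coding genes of the mitochondrial genome, 12 lay above 0, with a median of 0.60 (adjusted p = 8.81e-05, and 0.628 with an estimated correlation). MT-ND5 averaged 49527 ± 13714 in ALDH high and 30781 ± 17546 in ALDH low, and MT-ND3, the exception, 14223 ± 4244 and 15323 ± 1742. Without ALDH low 1, the median was 0.12 and the list was not called. Mitochondrial transcripts took 4.90%, 2.89% and 4.90% of the reads in ALDH high 1, 2 and 3 and 2.01%, 4.55% and 2.996% in ALDH low 1, 2 and 3 (two-sided exact permutation p = 0.3). Of 14 listed Hedgehog pathway genes, 8 were in the table. All 8 lay above 0, with a median of 0.28 (adjusted p = 0.00814, and 0.628 with an estimated correlation). Among them CDON, a co-receptor, averaged 737 ± 91.8 and 528 ± 118, and GLI1, a target of the pathway, 133 ± 49.8 and 115 ± 53.6. Of 51 DNA replication and E2F genes, 42 lay above 0, with a median of 0.10 (adjusted p = 0.0234, and 0.848 with an estimated correlation), as in POLE at 1358 ± 96.6 and 1036 ± 183. Of 20 listed Wnt and beta-catenin targets, 14 were in the table. Of these, 12 lay above 0, with a median of 0.20 (adjusted p = 0.05, just under the threshold, and 0.628 with an estimated correlation). AXIN2, a feedback target of Wnt signalling, averaged 167 ± 16.2 and 150 ± 24.0. Without ALDH low 3, the Hedgehog, replication and Wnt lists were not called, with medians of 0.17, 0.08 and 0.23, and without ALDH low 1 the replication and Wnt lists were not called, at −0.02 and 0.05. Without ALDH high 1 or without ALDH high 3 these last 2 lists were not called either, at 0.08 and 0.16 without ALDH high 1 and 0.07 and 0.19 without ALDH high 3. The oxidative phosphorylation list was also lost without ALDH high 2, at −0.03. Once a trend with gene length and GC content was removed, the Hedgehog and Wnt lists were not called, at 0.15 and 0.12. The Wnt list was also not called with edgeR on the recovered reads, at 0.18, or with mitochondrial genes left out, at 0.26, and neither it nor the replication list was called without a mean-variance trend.

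**Figure D4:**
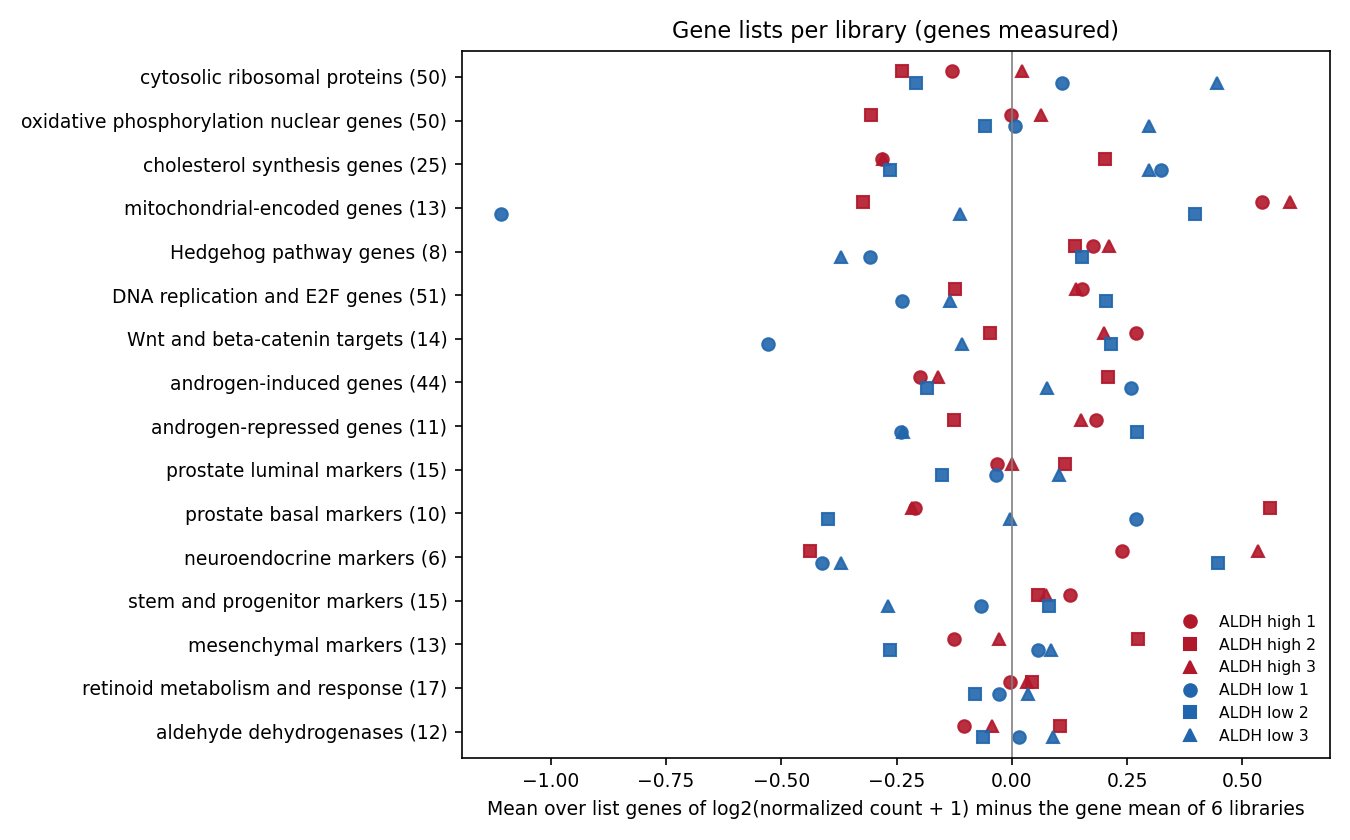
Mean over the genes of a list of log2(normalized count + 1), each gene taken relative to its mean over the 6 libraries, per library (red, ALDH high; blue, ALDH low; marker shape, replicate number; number of genes in parentheses; no means drawn). The 7 lists called by camera with its preset correlation stand at the top, and mitochondrial-encoded genes range from −1.11 in ALDH low 1 to 0.60 in ALDH high 3.

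Markers of other cell types were few in the table. It held 3 of 11 endothelial, 2 of 13 fibroblast and 1 of 14 leukocyte markers, too few for the list test. The leukocyte marker CD68 averaged 23.5 ± 7.90 in ALDH high and 23.7 ± 3.97 in ALDH low (SD, n = 3 each), and the fibroblast marker COL1A1, which some carcinoma cells also express, 1646 ± 159 and 1229 ± 353. The 10 most abundant genes took 6.44% ± 0.24 of the reads in ALDH high and 6.68% ± 0.36 in ALDH low (two-sided exact permutation p = 0.4, smallest possible 0.1).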

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

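Of the tests below, those of the exchange of the samples numbered 2 and of other splits of the samples were chosen after the result was seen, as was leaving out both samples numbered 2. The estimated correlation was listed beforehand, but what it would show was written down only after its result was seen. The tests of gene length and GC content, of mitochondrial transcripts and of single libraries had their expected outcomes written down before they were run. Groups of 3 samples were too small to look for single outlying values.

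Reads of ERCC spike-in sequences, synthetic control RNAs, appear in the table and are part of the read totals. They made up 0.487% of the reads over all libraries, above the limit that a count of 0 allows. Their share was 0.630%, 0.399% and 0.403% in ALDH high 1, 2 and 3 and 0.491%, 0.556% and 0.448% in ALDH low 1, 2 and 3 (two-sided exact permutation p = 0.8, smallest possible 0.1). The 25 spike-ins with a mean of at least 100 had a median SD of 0.10 on the log2 scale once each library's own offset was removed, against 0.23 for genes of that level.

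The split of the 6 samples into ALDH high 1, ALDH high 3 and ALDH low 2 against ALDH high 2, ALDH low 1 and ALDH low 3 called 789 genes with limma and 814 with edgeR, while the labelled split called 0, so that all 10 splits, too few for a share under 0.05, match it by construction. Removing a trend with gene length and GC content raised the count from 789 to 1535, which is 1.95 times. This argues against that trend as the whole cause of this structure across the labels. Leaving out mitochondrial genes kept 0.958 of the 789, at 756. Mitochondrial transcripts took only 2.01% (ALDH low 1) to 4.90% (ALDH high 3) of the reads. Leaving them out could thus hardly have lowered the count, and no conclusion is drawn from that test. An exchange of ALDH high 2 and ALDH low 2 stays open as a candidate explanation, because both, 2 of 2, had a higher mean correlation with the other group's samples numbered 1 and 3 (0.992 against 0.974 for ALDH low 2, and 0.982 against 0.977 for ALDH high 2). For ALDH high 2 this mean rests on ALDH low 1 (0.987), since its value with ALDH low 3 (0.9768) lay below those with its own group (0.9775 and 0.9770) and that with ALDH low 2 was 0.980. By the chi-square per gene it was nearest to ALDH low 2 (41.8), then to its own group (51.3 and 52.7), then to ALDH low 1 and 3 (64.0 and 91.7). Its median absolute log2 difference was 0.249, 0.282, 0.290, 0.255 and 0.395 in the same order. In the 107 genes called without both samples numbered 2, however, ALDH high 2 lay nearer to the ALDH low samples in 103. ALDH low 2 lay nearer to the ALDH high samples in 107. The measures across all genes thus do not agree on the place of ALDH high 2, while these 107 genes set it with ALDH low. A state of culture or handling that the labels do not record is not excluded.

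The 7 lists called by camera between the labelled groups all lost their call with a correlation estimated from the data (0 kept). That correlation ran from 0.145 for the Hedgehog list to 0.896 for mitochondrial-encoded genes, with 0.742 for ribosomal proteins, against the preset 0.01. However, camera's unadjusted p also rose for the ABC transporters, from 0.029 to 0.0787, where the estimated correlation was 0.0007, below the preset. The ABC list was not among the 7, so its rise shows only that this setting alters more than the correlation. How much of each of the 7 losses came from correlation was not separated. Genes of a list varying together between libraries stay open as a source of the small p. Without ALDH low 3, 1 of the 7 calls held, against 4 to 7 without any other library, and the median fell to near 0 for the ribosomal (−0.21 to −0.03) and oxidative phosphorylation lists (−0.15 to 0.01) but not for the Wnt (0.20 to 0.23) or replication list (0.10 to 0.08), so this library stays open as the source of some lists and not of all 7. Removing a trend with gene length and GC content left 5 of the 7 calls, all but the Hedgehog and Wnt lists, which argues against that trend as the source of those 5. With the preset correlation, other splits of the 6 samples called up to 14 lists, and 6 of the 10 splits, the labelled one included, called at least 7, where 10 splits are too few for a share under 0.05, while with an estimated correlation the split with 14 lists called 1 and each of the other 9 called 0. A difference tied to aldehyde dehydrogenase activity, the only biological explanation the design offers, was tested only as the labelled comparison itself.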

How the results depend on the processing

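Alternatives added after seeing the data were edgeR on the recovered reads, TMM factors, no mean-variance trend, removal of a length and GC trend, both samples numbered 2 left out, and mitochondrial genes left out. The count of 0 genes changed, in either direction and at least 2-fold, was also 0 in every fit listed beforehand, among them DESeq2, limma-voom, robust edgeR, the test against a 1.5-fold change and each single library left out. It moved only with both samples numbered 2 left out. Limma then called 107 genes, 75 higher and 32 lower, all 107 at least 2-fold, 12 of them members of the lists, and camera called 15 lists. All 107 genes were also called by the split of ALDH high 1, ALDH high 3 and ALDH low 2 against the other samples. That split keeps the remaining libraries on the same sides, so this overlap is partly built in. The 107 genes follow that arrangement across the labels, whose cause was not tested by these fits. The number of called lists, 7 in the main test, was 0 with an estimated correlation and 0 with fry, whose smallest adjusted p was 0.854, and ran from 1 to 14 when 1 replicate was left out. The median of the replication and E2F genes ran from −0.0156 without ALDH low replicate 1 to 0.24 without ALDH low replicate 2; the cause of the change in sign was not tested. Under other size factors, filters and pseudocounts the called lists numbered 7 to 9, against 6 with mitochondrial genes left out and 5 without a mean-variance trend or with the length and GC trend removed. Of 598 log2 differences of 24 genes (the aldehyde dehydrogenases, KLK3 and genes of smallest p) under alternatives, 583 moved by less than their standard error and none became significant, while 10 changed sign, 5 of them without ALDH low 3. The share of variance on the first principal component, taken there from log2(normalized count + pseudocount), ran from 61.6% to 76.8%, and from 64.3% to 75.3% with 1 replicate left out. The correlations of same-numbered deviations were −0.35, −0.51 and −0.04, which gave no sign that the replicate numbers pair the samples. They cannot exclude pairing, because same-numbered samples lay on opposite sides of the first principal component, which by itself pushes these values below 0. With the replicate block, limma called 0 genes and camera 6 lists, all but the Wnt list, and edgeR with the block called 0 genes. No scaling moved the median of all genes by over 0.1. At these depths and with the simulated spread, limma recovered 87 of 100 4-fold changes and 51 of 100 2-fold changes among 16000 genes, so smaller changes would often be missed. The simulation drew genes independently and lacked the arrangement across the labels, so these counts do not give the recovery in the real libraries.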

Other observations

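The values in this part were chosen after the data were seen and are given as values per library.

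In several gene groups the library values lay with ALDH high 1, ALDH high 3 and ALDH low 2 on one side and ALDH high 2, ALDH low 1 and ALDH low 3 on the other. For this split of the samples camera called 14 lists with its preset correlation and 1 with an estimated one. The split was itself found from the expression values of these libraries, so these calls describe it and are no test of the lists. The share of mitochondrial reads was 4.90%, 4.90% and 4.55% in the first 3 libraries and 2.89%, 2.01% and 2.996% in the others. The mean of the 44 androgen-induced genes, relative to each gene's mean over all libraries, was −0.20, −0.16 and −0.18 on the log2 scale in the first 3 libraries and 0.21, 0.26 and 0.08 in the others, in the order just named. The 11 androgen-repressed genes stood at 0.18, 0.15 and 0.27 and at −0.13, −0.24 and −0.24. DDC, an androgen-repressed gene encoding aromatic amino acid decarboxylase, had 1046, 1136 and 1022 normalized reads and 239, 269 and 333. CAMK2N1, a gene repressed by androgen that encodes an inhibitor of a calcium-dependent kinase, had 745, 722 and 625 and 77.6, 59.8 and 141. Replication-dependent histone transcripts, 9 genes, stood at −0.49, −0.37 and −0.70 and at 0.37, 0.55 and 0.62. The 51 DNA replication and E2F genes went the other way, at 0.15, 0.14 and 0.20 and at −0.12, −0.24 and −0.13. Of 28 listed neuroendocrine markers only 6 were in the table, at 0.24, 0.53 and 0.45 and at −0.44, −0.41 and −0.37. Their mean covers a small part of the list and does not show a neuroendocrine state. ENO2, a neuron-specific enolase that is also in the hypoxia and glycolysis list, had 2421, 2850 and 2172 reads and 1193, 1111 and 1432.

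The nuclear long noncoding RNA NEAT1 (chromosome 11) had 30580, 32286 and 23818 reads in the same 3 libraries and 12348, 9200 and 8679 in the others. GSTA1, a glutathione transferase that has close paralogs, had 485, 484 and 429 and 1506, 2271 and 2301. RDH11, a retinal reductase, had 6853, 6981 and 7589 and 14909, 13632 and 15184. The mean of the 12 aldehyde dehydrogenases had the same arrangement of signs with smaller values, at −0.10, −0.04 and −0.06 and at 0.11, 0.02 and 0.09. These signs rest in part on ALDH1L1, the least abundant member, with 4.19, 5.72 and 6.83 reads and 11.9, 19.1 and 11.8. ALDH18A1 did not follow the arrangement, at 4420, 4350 and 4630 and at 5059, 3608 and 4185. The estimated correlation of the list was 0.003, so the mean does not show that the family moved together. The authors' deposited table has no p for 2 rows. These are SDC2, a syndecan gene with 135, 146 and 146 reads in the first 3 libraries and 7.30, 6.06 and 3.21 in the others, and AC069228.1, with 453, 426 and 379 and 28.3, 45.05 and 25.7.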
